A study of Homo sapiens with 12 samples.

How the data were processed

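Gene expression was measured on 12 Illumina bead arrays hybridized with RNA of HT115 colorectal cancer cells. The cells carried either an shRNA against UGT1A_i2, the alternative transcripts of the UGT1A gene, or a non-target shRNA. Per the labels, each line was left untreated, given vehicle (0.1% DMSO) for 48 h, or given SN-38 at 0.5 µM for 48 h, with 2 arrays in each of the 6 groups. The labels do not state whether the 2 arrays of a group came from separate cultures, so every p-value measures only the spread between these samples. The DMSO content of the SN-38 dishes is not stated either.

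Per the file headers, the deposited non-normalized table held 1 signal intensity for each of 47323 probes on each array, on a linear scale with no background subtracted. Beside each intensity stood a detection p-value, per the file headers, which ranks the probe among negative control probes of the same array. The deposited matrix held values on a log2 scale, normalized by the authors in a way the labels do not name. In that matrix every array had the same median of 6.465, and each array's ranks were identical to those of its intensities (Spearman's rho across probes 1). It correlated with quantile-normalized log2 intensities at r = 0.99997 across probes on every array. A scanner report served for probe annotation only, and 89 columns of per-sample values that no label maps to a sample were not used. That report holds negative control probes for part of the arrays only, so the background was estimated from the detection p-values, which exist for all 12.

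Intensities were background-corrected, quantile-normalized and log2-transformed with neqc (offset 16) in limma 3.58.1 under R 4.3.3. Quantile normalization gives all arrays the same distribution, so a rise or fall is relative to the other genes. A change shared by most genes could not be seen, and a nearly even split of rises and falls is in part set by this step. A probe was kept when its detection p was under 0.05 on at least 2 arrays, which left 24786 probes. Genes were named through a table of GRCh38.p14 genes, by accession for 28588 probes, by symbol for 2514 and by an older symbol for 1213. The array's own name was used for 11738 probes, and 3270 had no name. The files name no genome build, so no coordinates are given, and chromosomes are those of the array annotation. The brightest probe on average stood for each gene, which gave 19121 genes, of which 13969 had a name that could be printed under the rule below and 5152 did not.

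One linear model with a mean for each of the 6 groups was fitted to all 12 arrays with limma, which left 6 residual degrees of freedom. Variances were moderated with eBayes with a mean-variance trend (median prior degrees of freedom 11.9), and all tests were two-sided. Of the 10 comparisons, 4 set i2 shRNA against non-target cells, averaged over the treatments and within each one. Another 4 set SN-38 against vehicle and vehicle against untreated cells in each line. The last pair tested whether those responses differed between the lines, as interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison, and intervals are at 95%. UGT1A values come from the same model fitted to all kept probes. Errors after ± are limma standard errors of a log2 difference.

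The 28 gene lists named below were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. Companion tests were camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance and compares them with no other genes. For each list the count of members past the threshold was taken over all genes and again adjusted over the list alone.

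The comparisons, the lists, the rule for named genes and the alternatives, except those named here as later, were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls among called genes of each of the 4 main comparisons, which were the knockdown average, SN-38 in each line and their interaction. It named the 5 largest each way elsewhere, and in each case every array of 1 group had to lie above every array of the other, except for the interaction. Up to 4 called members of each called list were added, as were every UGT1A probe and TOP1, the target of SN-38. Genes known only by a LOC or Hs. name were counted but not named, and 2 exceptions are marked in the text. Not every gene the rule picked is printed. Where a gene was detected on no array of the lower group, its fold is given as a lower limit from the lowest detected signal of each array.

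Alternatives covered quantile normalization with no background correction, the authors' values, scaling to equal array medians, and no detection filter or detection on all 12 arrays. They also covered the mean of a gene's probes, no variance trend, only the arrays of a comparison, the chip as a block, chip 2 alone, replicate numbers as a block with and without the chip, a 2-fold minimum, and leaving out each array. Chip 2 held 1 array of each i2 shRNA group and of untreated non-target cells. The spread of the fit to chip 2 alone thus came only from non-target vehicle and non-target SN-38 arrays. Added after the data were seen were untreated arrays as the control for SN-38 and leaving out replicate 1 of both untreated groups. Added at the same stage were the counts of metallothionein genes and of the genes for NKG2D ligands and the tests of the genomic span of genes.

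The method was tested on simulated data of 19121 genes with 200 changed. For the knockdown average it recovered 61.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold. For SN-38 in non-target cells these shares were 16.4%, 61.2% and 98.5%. For the interaction of SN-38 with the knockdown they were 2.99%, 17.9% and 92.4%. Each simulated comparison gave 5 to 14 false calls. These were 8 of 179 calls for the knockdown average and 13 of 127 for the knockdown in vehicle cells. The share of false calls could thus exceed the threshold of 0.05. Noise was drawn independently for each gene and array, with no array set apart. SN-38 called 3746 genes in non-target cells, far more than the 200 simulated, so the simulated shares may understate its recovery. The number of arrays limits the precision. Figures were drawn with matplotlib.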

Results

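The series asked how HT115 cells with a knockdown of UGT1A_i2 differ in gene expression, at rest and under SN-38. UGT1A encodes enzymes that attach glucuronic acid to drugs and bilirubin. Its i1 transcripts encode the active enzymes and its i2 transcripts, which end in another last exon, encode shorter proteins with no transferase activity. SN-38, the active form of irinotecan, traps topoisomerase 1 (TOP1) on DNA and is inactivated by UGT1A enzymes. Each of the 6 groups had 2 arrays, and 18504 to 20530 of 47323 probes (39.1% to 43.4%) were detected per array. Median raw intensity ran from 104.5 to 113.4. In normalized log2 signal across the 19121 genes, replicates correlated at 0.984 to 0.992 and arrays of different groups at 0.959 to 0.992.

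On the first principal component, which held 47.2% of the variance, the 4 SN-38 arrays lay at 44.2 to 51.1 and the other 8 at -30.5 to -19.3. The second component (15.7%) placed replicate 1 of both untreated groups at 32 and 37.5, apart from their replicates at -2.31 and 9.9 and from the 4 vehicle arrays at -23.4 to -20.4. The arrays lay on 2 chips, with 4 on chip 1 and 8 on chip 2. Both replicates of non-target vehicle and of non-target SN-38 cells were on chip 2, while the other groups had 1 array on each chip. Replicate numbers were not treated as pairs in the main fit. Deviations of replicates correlated across genes at -0.0026 to 0.10 between groups, apart from 0.33 between the untreated groups. The untreated groups thus shared part of their replicate difference, which the main fit left in the spread. Replicate numbers as a block were run as an alternative.

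UGT1A, the targeted gene, had 11 probes. By the array's coordinates 10 of them lay at least 31.1 kb upstream of the UGT1A1 probe, in the order of the alternative first exons, and so outside the last exons that tell i1 from i2. These 10 read i1 and i2 transcripts together and check nothing about the knockdown of i2, and the place of the UGT1A1 probe among the exons of that gene was not settled. UGT1A10 had group means of 8.73 ± 0.55 (SD, n = 2) in untreated non-target cells and 8.91 ± 0.16 in untreated i2 shRNA cells. Its means were 8.62 ± 0.16 and 8.77 ± 0.18 under vehicle, and 6.42 ± 0.20 and 6.70 ± 0.30 under SN-38, with the non-target value first. Averaged over treatments, i2 shRNA cells differed from non-target cells by 0.21 ± 0.14 (log2) for UGT1A10, 0.27 ± 0.17 for UGT1A1 and 0.19 ± 0.17 for UGT1A3. The 3 probes of UGT1A6 differed by 0.24 ± 0.11, 0.26 ± 0.13 and 0.19 ± 0.15. UGT1A7, UGT1A8 and UGT1A9, detected on 7, 7 and 3 arrays, differed by -0.13, -0.03 and 0.03. All of these had an adjusted p of 1, and the probes of UGT1A4 and UGT1A5 were detected on no array.

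**Figure D1:**
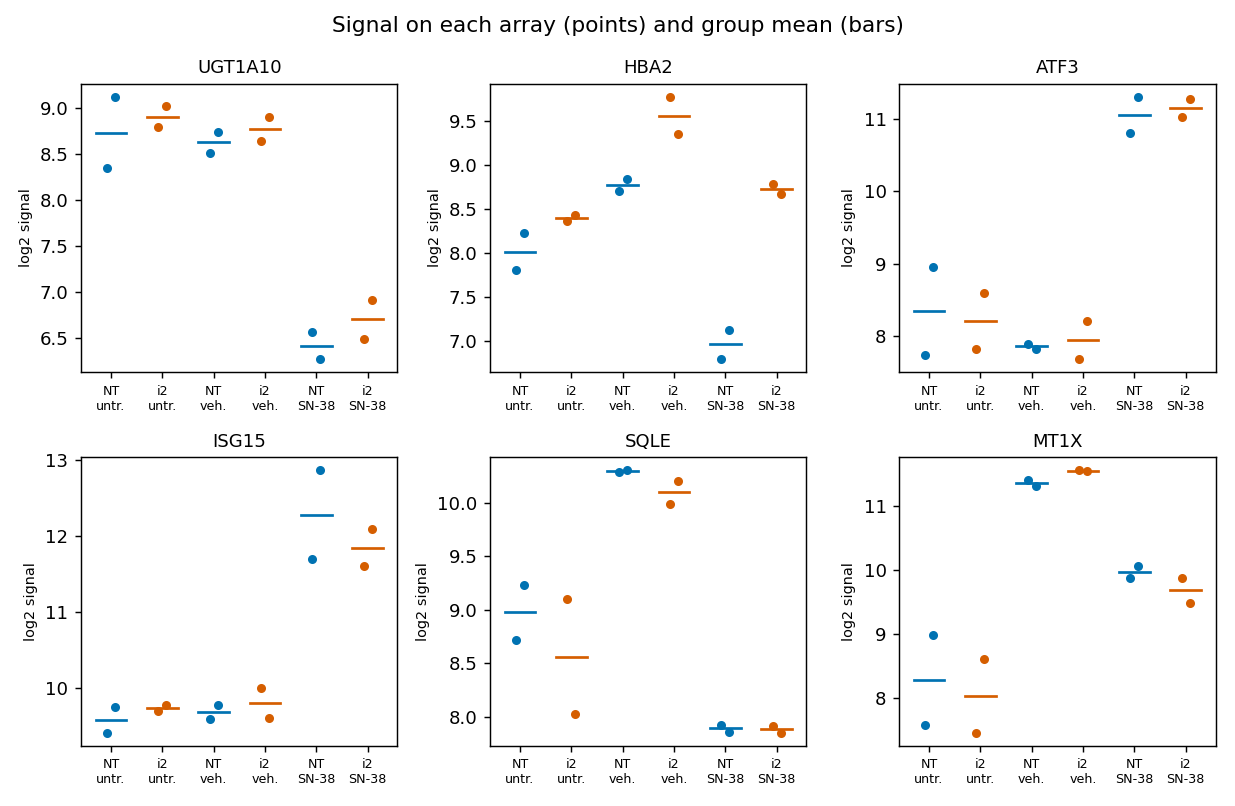
Normalized log2 signal of 6 genes on each array (points) with the mean of each group (bars), for non-target (NT) and i2 shRNA (i2) cells left untreated, given vehicle or given SN-38. UGT1A10 and SQLE were lower and ATF3 and ISG15 higher on all 4 SN-38 arrays than on the 4 vehicle arrays, HBA2 was higher in i2 shRNA cells in each treatment, and MT1X was highest on the 4 vehicle arrays.

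The first comparison asked what the i2 shRNA changed across treatments. The alpha-globin genes HBA1 and HBA2, which encode the alpha chain of hemoglobin, were higher in i2 shRNA cells. HBA1 rose by 1.12 ± 0.15 (log2, 2.17-fold, adjusted p = 0.0034, 6 arrays against 6) and HBA2 by 0.98 ± 0.11 (1.97-fold, adjusted p = 0.000908). The genes share nearly the same sequence, so the probes do not tell which of them changed. Across the 3 alpha-globin probes, every i2 shRNA array lay above every non-target array in each treatment. HBB, which encodes beta-globin, differed by 0.13 ± 0.18, and the other 10 measured leukocyte and endothelial markers had a median of -0.05 with 0 called by limma.

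Of 19121 genes, limma called 4 for this average, 2 higher and 2 lower, and 705 had an unadjusted p under 0.05 where chance alone gives 956. The lower pair, named after their values were seen, were HS.493947, a cluster of expressed sequences on chromosome 9, at -1.83 ± 0.17 (adjusted p = 4.14e-05), and LOC729841 at -0.44 ± 0.067 (adjusted p = 0.0199). Markers of goblet and secretory cells had a median of 0.19 over 11 measured members (camera adjusted p = 0.00467). None of the 11 passed over all genes, 1 rose adjusted over the list alone, and adjusted p = 0.347 with an estimated correlation. Without non-target SN-38 replicate 1 that list's median was 0.14 and its camera adjusted p 0.054. The other 27 lists were not called. On chip 2 alone, where each i2 shRNA group had 1 array, HBA1 differed by 0.86. Without i2 shRNA untreated replicate 1, 11 genes were called.

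Under SN-38, HBA1 was higher in i2 shRNA cells by 1.79 ± 0.26 (adjusted p = 0.0148) and HBA2 by 1.78 ± 0.20 (adjusted p = 0.000967), and both arrays of i2 shRNA cells lay above both of non-target cells. The HBA1 call was lost without any 1 of the 4 SN-38 arrays (1.60 to 1.99, adjusted p 0.0608 to 0.928), and the HBA2 call without i2 shRNA SN-38 replicate 1 (1.72, adjusted p = 0.0928). HBA1 was not called with quantile normalization (0.88, adjusted p = 0.139) or the authors' values (0.92, 0.124), nor HBA2 with the mean of its probes (1.19, 0.12). The second HBA2 probe differed by 0.61 under SN-38, 0.64 in untreated and 1.18 in vehicle cells, so a larger difference under SN-38 was not shared by all probes. HBA1 and HBA2 were the 2 genes called under SN-38, with 446 at an unadjusted p under 0.05. In untreated cells limma called 1 gene, HS.493947, at -2.57 ± 0.29 (log2, adjusted p = 0.000997). In vehicle cells it called 0, with a lowest adjusted p of 0.999 and 706 genes at an unadjusted p under 0.05, and no alternative run called any there.

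Cholesterol synthesis genes had a median of -0.22 in untreated i2 shRNA cells over 25 measured members (camera adjusted p = 0.00422). None passed over all genes, 1 fell adjusted over the list alone, and adjusted p = 0.955 with an estimated correlation. Without non-target untreated replicate 2 the median was -0.08 (camera adjusted p = 0.727), and without i2 shRNA untreated replicate 2 it was -0.05 (0.67). Interferon-stimulated genes had a median of -0.28 in i2 shRNA cells under SN-38 over 51 measured members (camera adjusted p = 6.8e-05). None passed over all genes or adjusted over the list alone, and adjusted p = 0.857 with an estimated correlation. That median turned to 0.14 (camera adjusted p = 0.0142) without non-target SN-38 replicate 2, and it was -0.05 (0.71) without i2 shRNA SN-38 replicate 1. The count of 2 genes under SN-38 fell to 1 with the chip as a block and to 0 without i2 shRNA SN-38 replicate 1, and the count of 1 in untreated cells was 16 without i2 shRNA untreated replicate 1. In untreated cells chip 2 alone gave 422 genes, but its 2 untreated arrays lay on opposite sides of the split seen on the second principal component. Differences between the untreated lines on chip 1 and on chip 2, each with 1 array per line, correlated at r = -0.32 across all genes. Each chip set replicate 1 of 1 line against replicate 2 of the other. Across genes, the differences between the lines in the 3 treatments correlated with each other at 0.0027 to 0.048.

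The second comparison asked what SN-38 did to non-target cells relative to vehicle. SQLE, an enzyme of cholesterol synthesis, changed by -2.40 ± 0.25 (log2). DDIT3 and ATF3, transcription factors of the stress response, rose by 3.23 ± 0.37 and 3.20 ± 0.31. UGT1A10 changed by -2.21 ± 0.24 (adjusted p = 3.27e-06) and the 3 probes of UGT1A6 by -1.47, -0.95 and -1.43, so that transcripts with these first exons fell. UGT1A7, detected on no SN-38 array of this line, was at least 1.88-fold lower (adjusted p = 0.0119), and UGT1A1, UGT1A3, UGT1A8 and UGT1A9 did not pass. TOP1 rose by 0.80 ± 0.23 (adjusted p = 0.0185). Its call was lost with arrays scaled to equal medians (0.72, adjusted p = 0.0768), without non-target SN-38 replicate 2 (0.69, 0.161), without non-target vehicle replicate 2 (0.56, 0.228) and against untreated cells (0.42, 0.225).

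Limma called 3746 of 19121 genes, 1867 higher and 1879 lower, and 1287 of them changed at least 2-fold. The largest rises were those of C17orf67 (4.79 ± 0.26), the glucose transporter SLC2A3 (4.33 ± 0.46), the fibrinogen beta chain FGB (4.17 ± 0.27) and the hair keratin-associated KRTAP3-1 (3.95 ± 0.26). Next came the intermediate filament gene PRPH (3.81), CD55, which protects cells from complement (3.45), the co-chaperone DNAJC12 (3.40), the killer-cell receptor KLRC2 (3.28), DDIT3 and the complement regulator C4BPB (3.22). Among the largest falls were those of the cytochrome CYP4F2 (-3.43 ± 0.22), MACROD1 (-3.33 ± 0.27), the histone H2BC9 (-3.12 ± 0.24) and the phospholipase PLA2G3, which was at least 5.83-fold lower. Also among them were the zinc transporter SLC39A11 (-2.94), GMDS, an enzyme of GDP-fucose synthesis (-2.90), PRUNE2 (-2.90), IMMP2L (-2.89) and the methyltransferase SMYD3 (-2.80). Each of these genes had an adjusted p of 5.91e-05 or lower, and both SN-38 arrays lay beyond both vehicle arrays. Some rises were smaller relative to untreated cells. CD55, for example, had non-target means of 8.96 untreated, 7.39 under vehicle and 10.84 under SN-38.

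Interferon-stimulated genes had the highest median, 0.97, with 32 of 51 measured members higher, 0 lower and 36 higher adjusted over the list alone (camera adjusted p = 5.24e-13; adjusted p = 0.333 with an estimated correlation). Among them ISG15 rose by 2.59, the transcription factor IRF7 by 2.52, the exonuclease ISG20 by 2.34 and the antiviral MX2 by 2.23. The 2 SN-38 arrays lay apart for ISG15 (SD 0.83), IRF7 (SD 0.55) and MX2 (SD 1.1), so the sizes of these rises are imprecise. ISG20 had non-target means of 11 untreated, 9.78 under vehicle and 12.12 under SN-38, so its rise over untreated cells was smaller. Genes of ATF4 and endoplasmic reticulum stress had a median of 0.69, with 18 of 35 higher and 3 lower, and 19 and 3 adjusted over the list alone (camera adjusted p = 2.79e-05; adjusted p = 0.431 with an estimated correlation and 0.0597 by fry). They included CHAC1 (2.29) and NUPR1 (2.24). Of 25 immediate early genes, which answer growth and stress signals within minutes, 15 rose and 1 fell, and 16 and 1 did adjusted over the list alone (median 0.56, camera adjusted p = 2.28e-07; adjusted p = 0.164 with an estimated correlation). The matricellular genes CCN2 (2.94) and CCN1 (2.91) and the phosphatase DUSP1 (2.58) were among them. Against untreated cells, a control added later, the median was 0.43 for the ATF4 list, with 14 higher and 2 lower (camera adjusted p = 0.00353; adjusted p = 0.634 with an estimated correlation), and 0.33 for immediate early genes, with 7 higher and 4 lower (0.0101 and 0.418).

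Of 35 p53 target genes, 12 rose and 3 fell, and 15 and 4 did adjusted over the list alone (median 0.38, camera adjusted p = 0.00402; adjusted p = 0.164 with an estimated correlation). GDF15, a stress cytokine, rose by 2.39, TP53INP1 by 2.14, SESN2 by 1.73 and GADD45A by 1.54. Vehicle means of these genes lay below untreated ones, so the rises over untreated cells were smaller. GDF15 had non-target means of 11.79 untreated, 10.27 under vehicle and 12.66 under SN-38, and TP53INP1 had 6.84, 5.94 and 8.09. Of 29 apoptosis regulators, which included inhibitors as well as promoters of cell death, 9 rose and 1 fell, and 12 and 3 did adjusted over the list alone (median 0.39, camera adjusted p = 0.00608; adjusted p = 0.164 with an estimated correlation). The promoters PMAIP1 (1.57) and BCL2L11 (0.89) rose, as did CFLAR (0.90), which blocks caspase 8, and the promoter BID changed by -1.01. BCL2L11 and CFLAR passed at limma adjusted p of 0.0489 and 0.0326, with SDs of 0.6 and 0.44 between the 2 vehicle arrays. With untreated cells as the control 11 of these regulators rose and 2 fell, with a median of 0.16 (camera adjusted p = 0.0331; adjusted p = 0.191 with an estimated correlation). Of 28 NF-kB and cytokine genes, 7 rose and 1 fell over all genes and adjusted over the list alone (median 0.24, camera adjusted p = 0.0136; adjusted p = 0.164 with an estimated correlation). The chemokines CXCL8 (2.76) and CCL5 (1.90), the subunit NFKB2 (1.65) and the inhibitor TNFAIP3 (1.34) were among those that rose.

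Cholesterol synthesis genes had the lowest median, -1.09, with 20 of 25 lower and 0 higher, and 20 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.71e-11; adjusted p = 0.164 with an estimated correlation). Besides SQLE, the sterol sensor INSIG1 (-2.09) and DHCR7 (-1.76) fell. Against untreated cells 9 of these genes fell and 1 rose, with a median of -0.45 (camera adjusted p = 0.00122; adjusted p = 0.418 with an estimated correlation). Of 28 fatty acid genes, 13 fell and 1 rose, and 13 and 2 did adjusted over the list alone (median -0.47, camera adjusted p = 0.000826; adjusted p = 0.165 with an estimated correlation). The desaturase SCD (-2.53), ACSL1 (-1.97), ACACA (-1.91) and the fatty acid synthase FASN (-1.63) led these falls. Of 40 mitosis genes, 18 fell and 0 rose, and 20 and 1 did adjusted over the list alone (median -0.41, camera adjusted p = 1.39e-07; adjusted p = 0.164 with an estimated correlation). The mitotic kinases PLK1 (-1.71), AURKA (-1.41) and BUB1 (-1.22) and the phosphatase CDC25C (-1.53) were among them. With that control 12 mitosis genes fell and 3 rose, with a median of -0.20 (camera adjusted p = 0.00511; adjusted p = 0.418 with an estimated correlation).

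Of 23 glycolysis genes, 11 fell and 3 rose, and 14 and 3 did adjusted over the list alone (median -0.38, camera adjusted p = 0.0136; adjusted p = 0.41 with an estimated correlation). ALDOC (-1.53) and HK2 (-1.15) fell while the glucose transporters SLC2A3 and SLC2A1 (1.15) rose. Of 27 NRF2 targets, 6 fell and 2 rose, and 8 and 2 did adjusted over the list alone (median -0.26, camera adjusted p = 0.0456; adjusted p = 0.165 with an estimated correlation). PIR (-1.82), the pentose phosphate enzyme TKT (-1.30) and ME1 (-1.12) fell, and OSGIN1 (0.94) rose. With the chip as a block the median of NRF2 targets was unchanged at -0.26, at a camera adjusted p of 0.051. Of 35 ribosome biogenesis genes, 8 fell and 1 rose over all genes and adjusted over the list alone (median -0.17, camera adjusted p = 0.00402; adjusted p = 0.383 with an estimated correlation). They included POLR1B (-1.17), LYAR (-0.91), WDR43 (-0.81) and NOC4L (-0.77). Of 18 heat shock genes, 4 fell and 0 rose over all genes and adjusted over the list alone (median -0.28, camera adjusted p = 0.0345; adjusted p = 0.43 with an estimated correlation). These were the chaperones HSPA8 (-1.03), HSPE1 (-0.84), HSP90AB1 (-0.70) and HSPD1 (-0.52). Against untreated cells neither ribosome biogenesis genes (median -0.05, camera adjusted p = 0.619) nor heat shock genes (-0.27, 0.149) were called. Without non-target SN-38 replicate 2 the adjusted p in camera was 0.0714 for glycolysis, 0.0714 for NRF2 targets and 0.16 for heat shock genes. Without non-target vehicle replicate 1 it was 0.0518 for ribosome biogenesis, 0.074 for NRF2 targets and 0.0686 for heat shock genes, and the NRF2 call was lost without any 1 of 8 arrays or with the chip as a block (0.051).

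Most lists not called in non-target cells held some called genes. Of 24 stem cell and Wnt target genes 10 fell and 4 rose (median -0.30, camera adjusted p = 0.085), and of 29 colonocyte markers 9 rose and 7 fell (median 0.10, adjusted p = 0.279). DNA replication genes had 5 higher and 2 lower of 42, DNA damage repair genes 2 higher and 6 lower of 37, and histone genes 6 higher and 4 lower of 27. Ribosomal protein genes had 11 lower and 1 higher of 74, oxidative phosphorylation genes 5 higher and 7 lower of 55, and proteasome genes 4 higher and 2 lower of 31. Hypoxia genes had 5 higher and 1 lower of 20, mesenchymal transition genes 5 and 3 of 21, and extracellular matrix and fibroblast markers 1 and 0 of 7. UGT genes had 2 higher and 4 lower of 15, drug metabolism and transport genes 8 and 4 of 41, leukocyte and endothelial markers 3 and 2 of 12, and goblet and secretory markers 0 and 0 of 11. Adjusted p in camera for these lists was 0.202 to 0.954, apart from the stem cell list. For oxidative phosphorylation genes the median was 0.04 and the mean -0.01.

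**Figure D2:**
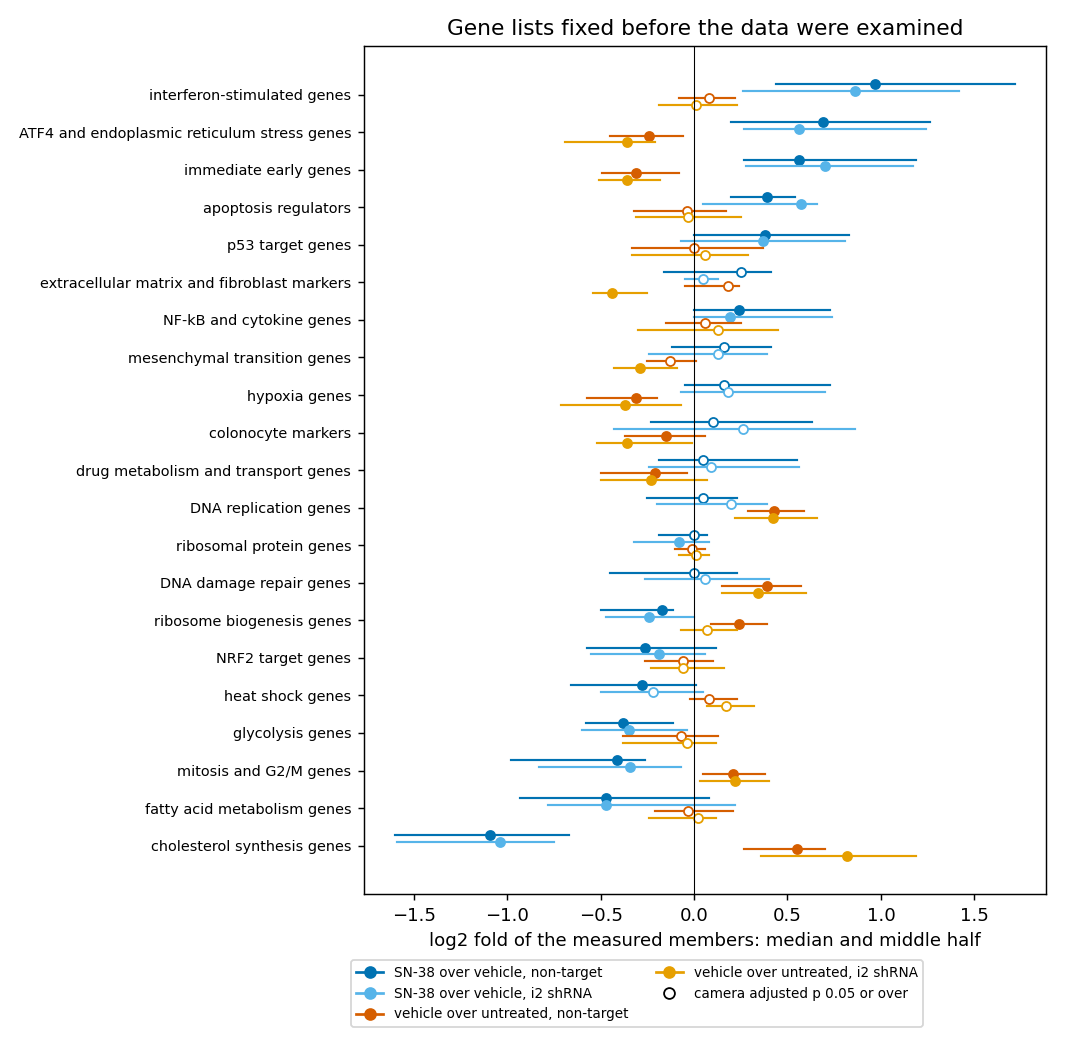
Median log2 fold (points) and interquartile range (lines) of the measured members of the gene lists called in at least 1 of 4 comparisons: SN-38 over vehicle and vehicle over untreated, in non-target and i2 shRNA cells. Filled points have a camera adjusted p under 0.05 at the preset correlation, none of which was kept with an estimated correlation; interferon-stimulated genes were highest (0.97 and 0.86) and cholesterol synthesis genes lowest (-1.09 and -1.04) after SN-38.

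Genes that fell under SN-38 tended to span more of the genome, a property examined after the values were seen. The trend was weak across 13899 genes, with Spearman's rho between span and fold of -0.16 in non-target and -0.078 in i2 shRNA cells. For vehicle over untreated it was 0.0071 and -0.062. Of 864 named genes over 200 kb, 208 (24.1%) fell and 31 (3.59%) rose in non-target cells, with a median of -0.26. Of 3512 genes under 10 kb, 299 (8.51%) fell and 553 (15.7%) rose, with a median of 0.07. In i2 shRNA cells 204 of the long genes (23.6%) fell and 40 (4.63%) rose. GMDS, PRUNE2, IMMP2L and SMYD3, among the largest falls above, are known as long genes. The span was known for 13899 of 13969 named genes, and in the dimmest of 3 equal classes by signal long and short genes differed by -0.12 in non-target cells (interval -0.16 to -0.06) and -0.05 in i2 shRNA cells (-0.13 to 0). The response of long relative to short genes differed between the lines by 0.12 (0.08 to 0.15, resampled over genes). For single arrays, signals were taken relative to each gene's mean over all arrays, so the values compare arrays with each other only. Long genes less short ones were at 0.16 and 0.12 in non-target and 0.06 and 0.10 in i2 shRNA cells under vehicle. Under SN-38 they were at -0.21 and -0.25 against -0.23 and -0.17. With 2 arrays per group the difference between the lines was left open.

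**Figure D3:**
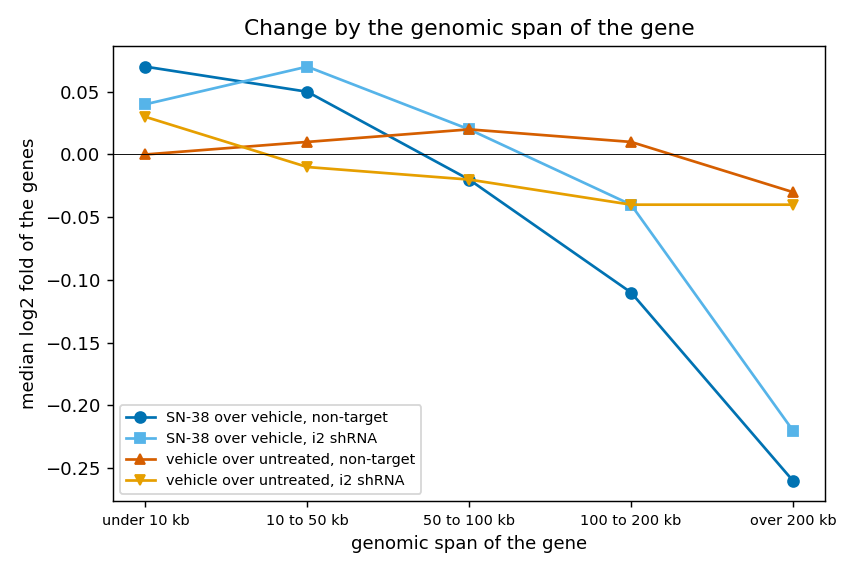
Median log2 fold of all named genes in 5 classes of genomic span, in SN-38 over vehicle and vehicle over untreated, for non-target and i2 shRNA cells. The medians after SN-38 were lowest in genes over 200 kb (-0.26 and -0.22), where those for vehicle were -0.03 and -0.04.

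Counts in non-target cells depended on both SN-38 arrays: without non-target SN-38 replicate 2 limma called 1925 genes. With arrays scaled to equal medians it called 2927, 1056 higher and 1871 lower, in place of the nearly even split.

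The third comparison asked the same of i2 shRNA cells. C17orf67 rose by 4.59 ± 0.26, FGB was at least 18.7-fold higher, and SLC2A3 rose by 4.39 ± 0.46. ATF3, the stress response factor, rose by 3.22 ± 0.31, and ULBP2 and RAET1L, surface ligands that alert natural killer cells, by 3.13 ± 0.19 and 3.23 ± 0.26. UGT1A10 changed by -2.07 ± 0.24 (adjusted p = 7.15e-06), the 3 UGT1A6 probes by -1.19, -0.89 and -1.42, and UGT1A8, detected on no SN-38 array of this line, was at least 1.46-fold lower (adjusted p = 0.0148). UGT1A7 differed by -0.24, and TOP1 by 0.28 ± 0.23 (adjusted p = 0.457), neither past the threshold.

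Limma called 3729 genes, 1838 higher and 1891 lower, of which 1250 changed at least 2-fold. Other large rises were those of PRPH (3.56), KLRC2 (3.47), C4BPB (3.45) and SELENOP, which carries selenium in plasma (3.16). Among the largest falls were those of MACROD1 (-3.69 ± 0.27), H2BC9 (-3.48 ± 0.24), CYP4F2 (-3.09 ± 0.22), PLA2G3 (at least 6.77-fold lower), GMDS (-2.97) and PRUNE2 (-2.91). LRP8, a lipoprotein receptor (-2.83), and the long noncoding MIR99AHG (-2.65) also fell. The metallothionein gene MT1H changed by -2.93 ± 0.37 against vehicle but rose by 1.57 (adjusted p = 0.00485) against untreated cells, a control added later.

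Interferon-stimulated genes had a median of 0.86, with 27 of 51 higher, 0 lower and 32 higher adjusted over the list alone (camera adjusted p = 2.42e-09; adjusted p = 0.421 with an estimated correlation). ISG20 (2.32), ISG15 (2.05), IRF9 (1.97) and IRF7 (1.96) were among them. Of 25 immediate early genes 13 rose and 2 fell, and 15 and 2 did adjusted over the list alone (median 0.70, camera adjusted p = 3.97e-07; adjusted p = 0.139 with an estimated correlation), with CCN2 at 2.95, CCN1 at 2.91 and DUSP1 at 2.59. Of 35 ATF4 and endoplasmic reticulum stress genes 16 rose and 2 fell, and 18 and 2 did adjusted over the list alone (median 0.56, camera adjusted p = 0.000104; adjusted p = 0.543 with an estimated correlation and 0.109 by fry), with DDIT3 at 2.79, CHAC1 at 2.09 and NUPR1 at 2.06. Of 29 apoptosis regulators 13 rose and 2 fell, and 15 and 2 did adjusted over the list alone (median 0.57, camera adjusted p = 0.000878; adjusted p = 0.0955 with an estimated correlation), with PMAIP1 at 1.49, CYCS at 1.09 and CFLAR at 1.09. Medians against untreated cells were 0.33 for immediate early genes (7 higher, 4 lower, camera adjusted p = 0.036), 0.25 for ATF4 genes (10 and 1, 0.0388) and 0.32 for apoptosis regulators (8 and 2, 0.00661). With an estimated correlation these calls were lost too (adjusted p = 0.474, 0.755 and 0.157). Of 35 p53 targets 14 rose and 3 fell, and 17 and 4 did adjusted over the list alone (median 0.37, camera adjusted p = 0.00195; adjusted p = 0.0955 with an estimated correlation). GDF15 (2.27), SESN2 (1.97), the cell cycle inhibitor CDKN1A (1.59) and GADD45A (1.48) rose. In this line GDF15 had means of 12.15 untreated, 10.62 under vehicle and 12.89 under SN-38. Of 28 NF-kB and cytokine genes 8 rose and 0 fell, and 9 and 1 did adjusted over the list alone (median 0.19, camera adjusted p = 0.00953; adjusted p = 0.139 with an estimated correlation), with CXCL8 at 2.60, NFKB2 at 1.63, CCL5 at 1.37 and RELB at 1.17.

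Of 25 cholesterol synthesis genes 20 fell and 0 rose over all genes and adjusted over the list alone (median -1.04, camera adjusted p = 2.94e-10; adjusted p = 0.147 with an estimated correlation), with SQLE at -2.22 and INSIG1 at -2.12. Against untreated cells 6 fell and 1 rose, with a median of -0.28 (camera adjusted p = 0.0434; adjusted p = 0.621 with an estimated correlation). Of 28 fatty acid genes 11 fell and 3 rose, and 12 and 4 did adjusted over the list alone (median -0.47, camera adjusted p = 0.00304; adjusted p = 0.241 with an estimated correlation), with SCD at -2.37, FASN at -1.65, ACSL1 at -1.63 and ACACA at -1.57. Of 40 mitosis genes 14 fell and 1 rose, and 15 and 3 did adjusted over the list alone (median -0.34, camera adjusted p = 7e-05; adjusted p = 0.246 with an estimated correlation), with PLK1 at -1.89, CDC25C at -1.41, AURKA at -1.23 and CDC20 at -1.17. Against untreated cells 11 mitosis genes fell and 6 rose, and the list was not called (median -0.08, camera adjusted p = 0.179). Of 23 glycolysis genes 9 fell and 4 rose, and 11 and 4 did adjusted over the list alone (median -0.35, camera adjusted p = 0.0394; adjusted p = 0.543 with an estimated correlation). ALDOC (-1.66) and HK2 (-1.07) fell and SLC2A1 (1.04) rose. Of 27 NRF2 targets 8 fell and 0 rose, and 10 fell adjusted over the list alone (median -0.19, camera adjusted p = 0.0166; adjusted p = 0.139 with an estimated correlation), with PIR at -1.79, AKR1C2 at -1.20 and TKT at -1.17, and a median of -0.35 against untreated cells (camera adjusted p = 0.0111; adjusted p = 0.161 with an estimated correlation). The glycolysis call was lost without any 1 of 5 arrays (adjusted p 0.0521 to 0.0705), the highest without i2 shRNA vehicle replicate 2.

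Of 35 ribosome biogenesis genes 9 fell and 1 rose, and 11 and 2 did adjusted over the list alone (median -0.24, camera adjusted p = 0.0087; adjusted p = 0.421 with an estimated correlation). UBTF (-0.95), NOC4L (-0.89), RRP9 (-0.84) and LYAR (-0.79) were among them, although UBTF differed by 0.01 against untreated cells, where the list was not called (median -0.10, camera adjusted p = 0.179). Of 74 ribosomal protein genes 18 fell and 0 rose over all genes and adjusted over the list alone (median -0.08, camera adjusted p = 0.0381; adjusted p = 0.241 with an estimated correlation), with RPL7 at -1.12, RPL14 at -1.06, RPL13 at -1.03 and RPS28 at -0.76. Without i2 shRNA vehicle replicate 2 or i2 shRNA SN-38 replicate 2 the adjusted p of that list was 0.0649 or 0.0585, and against untreated cells its median was -0.04 (0.0388, and 0.315 with an estimated correlation). Heat shock genes, called in the other line, had 4 of 18 lower here (median -0.22, camera adjusted p = 0.207). DNA replication, histone, repair, hypoxia, colonocyte, oxidative phosphorylation, UGT, drug metabolism, goblet, stem cell, mesenchymal, matrix, leukocyte and proteasome lists were not called, with adjusted p from 0.183 to 0.712; UGT genes had a median of 0.03 and a mean of -0.12. Log2 folds from chip 1 and from chip 2, each with 1 array per group, correlated at r = 0.7 across all genes. Without i2 shRNA SN-38 replicate 2 limma called 2005 genes, and with arrays scaled to equal medians it called 2868, 1688 higher and 1180 lower.

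The fourth comparison asked whether the knockdown changed the response to SN-38, and no gene did so past the threshold. Limma called 0 of 19121 genes for the interaction, with a lowest adjusted p of 1. At an unadjusted p under 0.05 there were 547 genes, against 956 by chance. A count under chance is no evidence of equal responses, and the knockdown comparisons had such counts too. The fit shared 1 spread estimate over all 6 groups, and the untreated replicates lay furthest apart on the second principal component. The alternatives also called 0 genes for the interaction in every case. Among them was the fit to only the arrays of the comparison, which leaves out the untreated arrays. That fit has fewer residual degrees of freedom, so it does not settle whether the shared spread made these tests too strict. UGT1A10 differed by 0.14 ± 0.34 in its response and TOP1 by -0.52 ± 0.32, each with an adjusted p of 1. Interferon-stimulated genes had a median of -0.16 (camera adjusted p = 0.193), and none of the 28 lists was called at the preset correlation, with an estimated correlation or by fry. Quantile normalization with no background correction and the authors' values each called 3 lists.

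Both lines shared most of the response. SN-38 called 2716 genes in both, 1347 higher in both, 1369 lower in both and 0 with opposite signs, where independent lists would share 179 and 186. Of the 3746 genes called in non-target cells 3689 (98.5%) had the same sign in i2 shRNA cells. Across all genes, which are not independent replicates, log2 folds of the lines correlated at r = 0.814 (Spearman's rho 0.71), with no array in common. For 11074 genes (57.9%), and for 3407 (71.6%) of the 4759 called in either line, the interval of the difference lay within 2-fold, so larger differences were not excluded for the rest. The median interval reached 0.747 (log2) to each side.

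**Figure D4:**
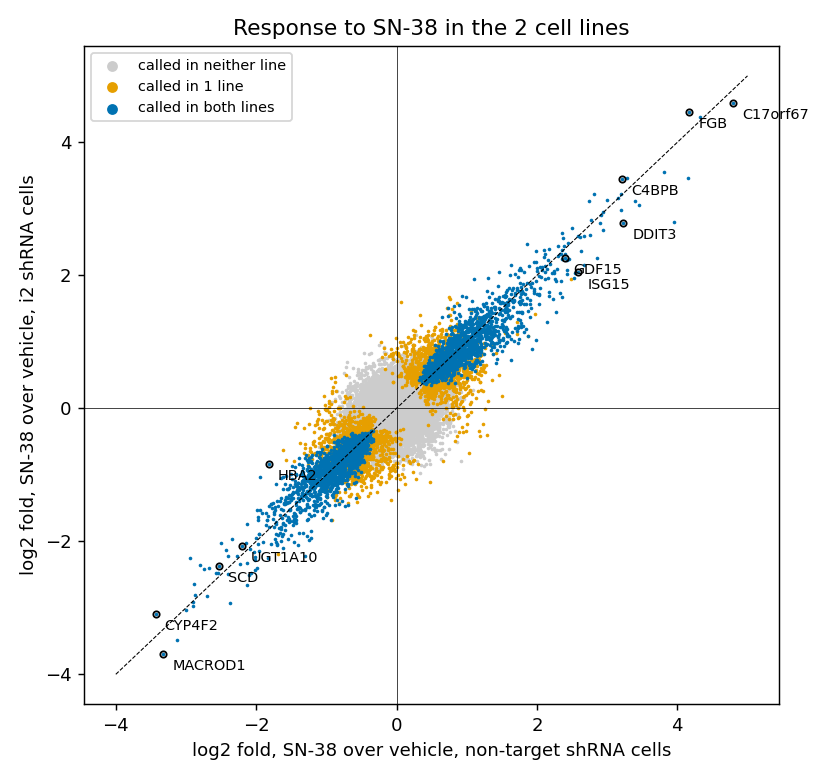
Log2 fold of each gene after SN-38 over vehicle in non-target cells (horizontal axis) and i2 shRNA cells (vertical axis), colored by the number of lines in which limma called it. Points follow the dashed line of equal response, and 2716 genes were called in both lines, none with opposite signs.

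The vehicle comparisons asked what 48 h with 0.1% DMSO changed relative to untreated cells. Genes of the metallothionein family, whose small proteins bind zinc and copper, rose in both lines, as did the pseudogene MT1IP of that family. In non-target cells MT1H rose by 4.05 ± 0.37, MT1G by 3.66 ± 0.51, MT1IP by 3.52 ± 0.38, MT1X by 3.08 ± 0.34 and MT2A by 3.05 ± 0.28. The i2 shRNA cells had MT1H higher by 4.50 ± 0.37, MT1G by 4.46 ± 0.51, MT1IP by 3.66 ± 0.38 and MT1X by 3.53 ± 0.34, and MT1M was at least 6.87-fold higher. These genes are close paralogs, so which of them changed is uncertain, and their adjusted p was 0.00189 or lower.

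PIGR, which carries antibodies across epithelia, changed by -2.45 ± 0.37 in non-target cells (adjusted p = 0.00468). The GTPase gene RRAGD (-1.98), the synapsin SYN2 (-1.89), MAPT, which encodes tau (-1.88), and the elongation factor EEF1A2 (-1.78) also fell there. In i2 shRNA cells ZNF467 (-2.29), LEMD1 (-1.83), RRAGD (-1.82), TXNIP, an inhibitor of thioredoxin (-1.79), and the autophagy gene GABARAPL1 (-1.73) fell. These falls were larger on chip 2, which held untreated replicate 1 of this line. ZNF467 changed by -1.27 on chip 1 and -3.31 on chip 2, and RRAGD by -1.03 and -2.62. UGT1A10 differed by -0.11 and -0.13 and TOP1 by -0.38 and 0.48 in non-target and i2 shRNA cells, none past the threshold. Limma called 82 genes in non-target cells (39 higher, 43 lower) and 391 in i2 shRNA cells (214 higher, 177 lower).

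Of 25 cholesterol synthesis genes 4 rose in non-target cells, 13 adjusted over the list alone (median 0.55, camera adjusted p = 1.52e-10; adjusted p = 0.292 with an estimated correlation). For i2 shRNA cells, 14 rose, 17 adjusted over the list alone (median 0.82, camera adjusted p = 1.65e-12; adjusted p = 0.193 with an estimated correlation). SQLE rose by 1.32 and 1.54, HMGCS1 by 1.21 and 1.61, and IDI1 by 1.16 and 1.82, with the non-target value first, and ACAT2 by 0.84 in non-target cells. Of 42 DNA replication genes 2 rose in non-target cells, 14 adjusted over the list alone (median 0.43, camera adjusted p = 2.29e-12; adjusted p = 0.341 with an estimated correlation), with POLE at 0.75 and E2F8 at least 2.07-fold higher. With the i2 shRNA, 5 rose, 18 adjusted over the list alone (median 0.42, camera adjusted p = 7.89e-10; adjusted p = 0.339 with an estimated correlation), among them CCNE2 (1.54), UHRF1 (0.90), MCM6 (0.66) and PCNA (0.66). Without i2 shRNA untreated replicate 1, CCNE2 differed by 0.82 (adjusted p = 0.2). Of 37 DNA damage repair genes 0 and 2 rose over all genes, and 13 and 12 adjusted over the list alone (medians 0.39 and 0.34, camera adjusted p = 2.86e-08 and 6.32e-07; adjusted p = 0.307 and 0.257 with an estimated correlation), with NBN at 0.72 and MSH6 at 0.60 in i2 shRNA cells. Of 40 mitosis genes 0 and 2 rose, 1 and 5 adjusted over the list alone (medians 0.21 and 0.22, camera adjusted p = 0.00019 and 0.000577; adjusted p = 0.341 and 0.339 with an estimated correlation), with KIF11 and CDCA3 at 0.62 in i2 shRNA cells. Ribosome biogenesis genes had a median of 0.24 in non-target cells with 0 of 35 called either way (camera adjusted p = 0.000103; adjusted p = 0.34 with an estimated correlation). Without non-target untreated replicate 1 the medians in that line were lower, at 0.17 for DNA replication genes, 0.19 for DNA damage repair genes, 0.16 for mitosis and G2/M genes, 0.31 for cholesterol synthesis genes and 0.15 for ribosome biogenesis genes. Without i2 shRNA untreated replicate 1 they were 0.35 for DNA replication genes, 0.28 for DNA damage repair genes and 0.10 for mitosis and G2/M genes in i2 shRNA cells, with the calls kept in both lines.

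Of 25 immediate early genes 1 fell in non-target cells and 5 in i2 shRNA cells, and 6 and 9 adjusted over the list alone (medians -0.31 and -0.36, camera adjusted p = 4.86e-05 and 1.44e-05; adjusted p = 0.292 and 0.193 with an estimated correlation). FOS changed by -1.04 and -0.87, and in i2 shRNA cells DUSP4 changed by -1.25, DUSP6 by -1.19, and FOSB was at least 1.85-fold lower. Of 20 hypoxia genes 1 and 3 fell, and 3 and 5 adjusted over the list alone. Their medians were -0.31 and -0.37 (camera adjusted p = 0.000203 and 0.000959, and 0.409 and 0.413 with an estimated correlation). In i2 shRNA cells the hypoxia median was -0.5 on chip 1 and 0.03 on chip 2, so the fall was not seen on chip 2. NDRG1 changed by -0.73 and -0.88, and MXI1 (-1.18) and BNIP3L (-0.93) fell in i2 shRNA cells. Of 41 drug metabolism genes 0 and 3 fell, 3 and 6 adjusted over the list alone (medians -0.21 and -0.23, camera adjusted p = 0.000359 and 0.00203; adjusted p = 0.292 and 0.208 with an estimated correlation), with GSTM2 (-1.25), CYP4F3 (-1.05) and GSTM4 (-0.90) in i2 shRNA cells. Without untreated replicate 1 of the same line the medians of drug metabolism and transport genes were -0.13 and -0.07. Colonocyte markers had medians of -0.15 and -0.36, with 1 of 29 (CA2, -0.78) and 0 lower over all genes and 3 and 5 adjusted over the list alone (camera adjusted p = 0.049 and 0.00217; adjusted p = 0.292 and 0.193 with an estimated correlation). In i2 shRNA cells 21 mesenchymal genes had a median of -0.29 with 0 called and 1 lower adjusted over the list alone (camera adjusted p = 0.00235; adjusted p = 0.193 with an estimated correlation). There 7 matrix and fibroblast markers had a median of -0.44 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.00633; adjusted p = 0.193 with an estimated correlation). Without non-target vehicle replicate 1 the adjusted p of the hypoxia list in non-target cells was 0.089, and without i2 shRNA vehicle replicate 1 it was 0.271 for hypoxia and 0.0626 for matrix genes in i2 shRNA cells. The colonocyte call in non-target cells was lost without any 1 of 10 arrays (0.0501 to 0.198), the highest without non-target untreated replicate 1. Other lists were not called, p53 targets (medians 0 and 0.06) and interferon-stimulated genes (0.08 and 0.01) among them.

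Genes of ATF4 and endoplasmic reticulum stress had medians of -0.24 and -0.36 under vehicle with 0 of 35 called, and 2 lower and 1 higher in non-target cells and 7 lower and 3 higher in i2 shRNA cells adjusted over the list alone (camera adjusted p = 0.0312 and 0.00565; adjusted p = 0.734 and 0.718 with an estimated correlation). Those medians moved to 0.09 without non-target untreated replicate 2 and to -0.01 without i2 shRNA untreated replicate 2. Limma called 0 genes for the difference between the lines in the response to vehicle, with a lowest adjusted p of 1 and 662 at an unadjusted p under 0.05, and called 125 on chip 2 alone. Without non-target vehicle replicate 1 the count in non-target cells was 13, and without non-target untreated replicate 2 it was 920. In i2 shRNA cells it was 25 without i2 shRNA vehicle replicate 1 and 1045 without i2 shRNA untreated replicate 2. Log2 folds of i2 shRNA cells from the 2 chips correlated at r = 0.24 across all genes, and non-target vehicle arrays lay on 1 chip. With the chip as a block 23 genes were called in non-target cells. Scaled to equal medians, i2 shRNA cells had 308 called genes, 214 higher and 94 lower.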

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

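Tests added after the results were seen were those with untreated arrays as the control and without replicate 1 of both untreated groups. With SN-38, 13 lists were called in each line, and normalization, filter and fit left the gene counts within 1.5 times of 3746 and 3729, except that a 2-fold minimum gave 1287 and 1250. Against untreated cells the counts were 4004 and 4055, of which 2637 and 2524 were shared, and MT1H turned to 1.57 and UBTF to 0.01 in i2 shRNA cells, since vehicle and untreated cells differed for both. A call is counted as kept here if the value stayed called or stayed uncalled, as many UGT1A and TOP1 values did. Of 271 named values, 265 kept their call with quantile normalization and no background correction, 265 with the authors' values and 257 with median scaling. The authors' values nearly equal quantile-normalized ones (r = 0.99997), so these 2 settings are not separate checks. Most named values were picked as large called changes in these data, so the counts do not speak for other calls. Calls were kept by 254 with the chip as a block, 251 on chip 2 and 256 with no detection filter. They were kept by 248 with the mean of probes and 225 with no variance trend. No value called in either run changed sign in these settings, but direction was not compared where neither run called. Against untreated cells 11 of 152 named SN-38 values lost their call, 2 gained one and 2 turned. Without replicate 1 of both untreated groups, 51 of 67 named values of the vehicle comparisons kept their call and 16 lost it. Scaling to equal medians moved the median of all genes in the interaction of SN-38 with the knockdown by 0.15.

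The 2 genes of the knockdown under SN-38 became 1 with quantile normalization, the authors' values, detection on all 12 arrays, the mean of probes, only the arrays compared, the chip as a block, chip 2 alone, and the replicate block with the chip, and 0 with no variance trend. The 4 genes of the knockdown average became 2 with detection on all 12 arrays or a 2-fold minimum and 26 on chip 2 alone. The 1 gene in untreated cells became 0 with detection on all 12 arrays or only the arrays compared and 422 on chip 2. The 82 genes of vehicle in non-target cells became 12 with no variance trend, 14 with only the arrays compared, 23 with the chip as a block, 298 with the replicate block, 135 with both blocks and 53 at 2-fold. The 391 in i2 shRNA cells became 38 with no variance trend, 118 with only the arrays compared, 1298 on chip 2, 802 with the replicate block, 722 with both blocks and 169 at 2-fold. The difference of the vehicle responses had 0 genes and 125 on chip 2. Without replicate 1 of both untreated groups vehicle gave 68 genes in non-target cells (36 shared) and 399 in i2 shRNA cells (236 shared). Counts on chip 2 alone rest on 1 array in most groups, so they say little about the spread within those groups. The causes of these changes were not tested.

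Gene lists called in the knockdown comparisons depended on the normalization. Quantile normalization gave 7 for the average, 7 untreated, 2 under vehicle and 2 under SN-38, and 3 and 1 for the interactions with SN-38 and vehicle. The authors' values gave 7, 6, 2 under SN-38, and 3 and 1. The chip block gave 2 untreated, 3 under SN-38 and 1 for the vehicle interaction. The replicate block gave 3 for the average and 3 untreated. In other comparisons the replicate block ended 3 list calls. With SN-38 these were NRF2 targets in non-target cells (camera adjusted p = 0.0546) and glycolysis genes in i2 shRNA cells (0.0562). The third was colonocyte markers under vehicle in non-target cells (0.0604). With an estimated correlation all 7 comparisons that had called lists had 0. By fry, the average, untreated and SN-38 knockdown comparisons and vehicle in non-target cells had 0, vehicle in i2 shRNA cells had 7, and SN-38 had 19 and 15.

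Leaving out 1 array, where the lone array of a group is assumed to vary like the other groups, gave 3 to 11 genes for the knockdown average, 1 to 16 untreated, 0 to 0 under vehicle and 0 to 4 under SN-38. SN-38 gave 1925 (without non-target SN-38 replicate 2) to 4193 genes in non-target cells and 2005 (without i2 shRNA SN-38 replicate 2) to 4221 in i2 shRNA cells. Both interactions stayed at 0 to 0. Vehicle gave 13 (without non-target vehicle replicate 1) to 920 (without non-target untreated replicate 2) and 25 (without i2 shRNA vehicle replicate 1) to 1045 (without i2 shRNA untreated replicate 2). Lists ran 1 to 7 for the average, 1 to 9 untreated, 0 to 1 under vehicle and 0 to 2 under SN-38, 10 to 15 and 11 to 13 for SN-38, 0 to 3 for its interaction, 7 to 10 and 8 to 13 for vehicle and 0 to 3 for its interaction. Of 600 list values 559 kept direction and call, 38 lost the call and 3 turned. Those were ATF4 genes under vehicle, whose median ran from -0.52 to 0.09 in non-target cells (highest without non-target untreated replicate 2) and -0.69 to -0.01 in i2 shRNA cells (highest without i2 shRNA untreated replicate 2, where camera gave the other direction). The third was the median of interferon-stimulated genes in the knockdown under SN-38, at -0.56 to 0.14 (highest without non-target SN-38 replicate 2). Of the genes called for SN-38 with several probes, 177 of 1192 in non-target cells and 187 of 1168 in i2 shRNA cells had a probe of the opposite sign, called in 9 and 6 genes.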

Other observations

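Of the tests below, only the count over other splits of the arrays was chosen before its result was seen; the rest, with both gene families, were chosen after. Genes for ligands of NKG2D, a receptor by which natural killer cells recognize stressed cells, rose with SN-38. Of 7 measured, a family looked up because ULBP2 and RAET1L were among the largest rises, 5 rose in each line (medians 1.99 and 2.37). ULBP2 rose by 2.99 and 3.13, RAET1L by 2.82 and 3.23, RAET1G by 2.36 and 2.64, ULBP1 by 1.99 and 2.37, and MICB by 1.35 and 0.98, with the non-target value first. MICA (0 and -0.12) and RAET1E (-0.12 and 0.02) did not pass, and these genes are partly close paralogs.

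Relative to untreated cells, 15 of 42 DNA replication genes were higher with SN-38 in non-target cells and 16 in i2 shRNA cells, with 0 lower. Their medians were 0.28 and 0.44 (camera adjusted p = 2.62e-05 and 2.22e-07, and 0.511 and 0.473 with an estimated correlation). Vehicle cells also had this list higher than untreated cells, with medians of 0.43 and 0.42. Relative to vehicle, the SN-38 medians were 0.05 and 0.20, and 5 genes rose and 2 fell in each line. The rise over untreated cells therefore cannot be credited to SN-38 itself.

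The knockdown average had 4 called genes, and chance was not excluded for that count. Of 100 splits of the arrays within treatments, drawn from 108, 32 gave as many genes, the real one included, and the highest other gave 209. The large counts came from a structure of the samples: 31 splits that put replicate 1 of both untreated groups on 1 side reached 209, while the 68 others gave at most 2. For alpha-globin, RNA from blood cells is argued against by HBB, which differed by 0.13 with an upper limit of 0.51, below the rise of HBA2 (0.98). A difference between the chips is argued against by HBA2 with the chip as a block (0.97, limma adjusted p = 0.012). On chip 2 alone HBA2 differed by 0.81 and HBA1 by 0.86. There each i2 shRNA group had 1 array, so only these sizes are given. An effect of the shRNA or of the separate derivation of the lines may remain, and these arrays cannot separate them.

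Genes that span over 200 kb were lower than short genes after SN-38, by -0.33 (-0.38 to -0.29) in non-target cells and -0.25 (-0.29 to -0.21) in i2 shRNA cells. A first test, whether this held in each of 3 equal classes of genes by signal, was met in the dimmest class of non-target cells (-0.12, interval -0.16 to -0.06) but undecided in that of i2 shRNA cells (-0.05, interval -0.13 to 0), and the brightest class was chosen after that was seen. There the differences were -0.51 and -0.38 (-0.52 to -0.25), which argues against dim probes as the whole cause. Differences of -0.38 and -0.32 against untreated cells argue against a length trend of the vehicle arrays as the whole cause. In vehicle over untreated, long genes differed from short ones by -0.03 (-0.06 to 0) in non-target and -0.06 (-0.09 to -0.04) in i2 shRNA cells. All intervals here resample genes, not arrays. A candidate explanation is that TOP1 trapped by SN-38 slows transcription of long genes, and the median of -0.26 in genes over 200 kb of non-target cells is in line with it but largely restates the pattern. Signals of single arrays were taken relative to each gene's mean over all arrays. On that scale long genes less short ones were at -0.25 to -0.17 with SN-38 and 0.06 to 0.16 on the other 8. The signs do not tell whether long or short genes were brighter on an array. No transcription was measured, so other effects of SN-38 on long genes stay open. The difference of 0.12 (0.08 to 0.15) between the responses of the lines stays open too, and rests on 2 arrays per group.

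Of 11 measured metallothionein genes, which include the pseudogenes MT1DP, MT1IP and MT1P3, 10 rose under vehicle in each line (medians 2.97 and 3.25). With SN-38 against vehicle 9 and 10 of them fell (-1.46 and -1.91). A difference between the chips is argued against by 10 called genes with the chip as a block, and replicate 1 of the untreated cells by 10 called without both of those arrays. SN-38 cells also exceeded untreated cells, by medians of 1.57 and 1.32. DMSO cannot be told apart from handling or time shared by the treated dishes, since the only vehicle arrays differ from untreated ones in all of these, and the labels give no DMSO content for SN-38 dishes.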
